A study of Mus musculus with 24 samples.

How the data were processed

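RNA was sequenced from the cortex of 24 mice aged 7.5 months, 1 library per mouse. All mice carried 5xFAD, a set of human transgenes, mutant amyloid precursor protein among them, that leads to amyloid plaques. The labels gave 4 genotypes with 6 mice each: wild type at both loci (WT), Trem2 knockout (Trem2KO), homozygous Plcg2 knockout (Plcg2KO) and heterozygous Plcg2 knockout (Plcg2HET). WT, Trem2KO and Plcg2HET held 3 males and 3 females each, and Plcg2KO held 4 males and 2 females. Mice are named here by genotype and by the code in the labels, which gives the sex and a number (M1, F3). No mice without 5xFAD were analysed here, so no level could be set against cortex free of the transgenes.

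The authors deposited a table of whole-number read counts per gene for 24421 genes, with exon coordinates and a summed exon length per gene, per the file headers. The submitters' processing notes name STAR 2.7.10a, featureCounts 2.0.3 and the mouse build mm10. A further table held expected counts, TPM and FPKM for each library together with an effective length, deposited by the authors under those names per the file headers. The tool that made the expected counts is not given in the sources used here, and neither is the strand setting of the counting. TPM, FPKM and effective lengths entered no test, and the deposited expected counts, rounded to whole numbers, were used only for an alternative fit.

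All statistics were computed from the deposited counts with R 4.3.3. Genes were kept by edgeR's filterByExpr with a minimum count of 10 by genotype, which left 16316 genes. Library sizes were scaled by TMM, and a quasi-likelihood model with robust fitting (edgeR 4.0.16) was fitted over all 24 libraries with 1 mean per genotype and a term for sex. The 4 genotypes therefore shared 1 estimate of the spread. Adjusted p-values are from edgeR's quasi-likelihood F-test with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower. Log2 fold changes are given with their standard errors. CPM values were scaled by TMM. Sex differences between genotype effects were tested as interaction contrasts in a model with 1 mean per genotype and sex. Plcg2 and Trem2 were also compared on log2(CPM + 0.5) by two-sided exact permutation tests of 6 against 6 libraries, whose smallest p is 0.00216.

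Before the data were examined, 41 lists of genes were fixed, of which 36 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the 36 lists, and again with the correlation estimated from the data and with fry. Of the 653 list genes, 626 were in the count table. The rule for named genes was also fixed beforehand. It took Plcg2 and Trem2, the 8 largest increases and 8 largest decreases among called genes with an average log2 CPM of at least 1, and the 3 members with the smallest p of each called list. The same was done for the microglial state and TREM2 signalling lists, called or not. The comparison of Plcg2KO with Plcg2HET and the comparison of the sexes took the 5 genes with the smallest p.

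Total counts ran from 36.3 to 83.0 M per library (M, 1e6 counts). No 2 libraries held identical counts, and correlations of log2 counts between libraries, with no filter or scaling, lay between 0.98 and 0.994. Sex-linked genes matched the labelled sex in 24 of 24 libraries. In counts simulated for Plcg2KO against WT over 16316 genes, the fit recovered 39 of 67 genes changed 1.5-fold (58.2%), 58 of 67 changed 2-fold (86.6%) and 65 of 66 changed 4-fold (98.5%), with 4 false calls among 166. The 1 shifted list was called, with 0 of the other lists called. Genes were drawn independently there, without trends shared across genes. The simulation therefore cannot show how many genes or lists are called by chance in the real libraries.

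Alternatives fixed beforehand were RLE size factors, no count filter, a mean CPM of at least 1, no sex term, the replicate code as a block, each sex alone, only the 2 groups compared, DESeq2 1.42.0, each library left out in turn, and estimated correlations. Alternatives added after the data were seen were the expected counts, offsets that remove trends with GC content and gene length, and a fit without the 3 libraries with over 5% of counts from Rn45s, a ribosomal RNA precursor. GC content was available for 15693 tested genes (96.2%). Genes whose spans overlap another gene, or that have close copies, can share or lose reads. Of 140 named genes, 32 overlapped another gene, among them B2m, P2ry12, H2-D1, Ifi27, 5031426D15Rik and the protocadherin gamma genes, and the values of MHC genes and other multigene families are uncertain for the same reason.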

Results

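The study measured gene expression in the cortex of 5xFAD mice that lacked Trem2, lacked Plcg2, were labelled heterozygous for the Plcg2 knockout, or were wild type at both loci. Trem2 encodes a lipid-sensing receptor of microglia, the resident immune cells of the brain, and Plcg2 encodes a phospholipase that acts downstream of immune receptors, TREM2 among them. The comparisons address how loss of either gene changes the microglial response to amyloid, and whether the effects resemble each other. Each genotype had 6 mice, and total counts per library were 43.9 to 71.3 M in WT, 54.8 to 83.0 M in Trem2KO, 49.4 to 81.5 M in Plcg2KO and 36.3 to 68.9 M in Plcg2HET.

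Libraries differed in ways that followed genotype in part. Rn45s took 29% of counts in Plcg2HET F3, 9.59% in WT F1 and 5.29% in Plcg2HET F1, and at most 3.5% in every other library. The trend of each library's deviations with GC content, a Spearman correlation across genes, was negative in 6 of 6 Plcg2KO libraries (-0.566 to -0.285) and positive in 5 of 6 Trem2KO libraries (-0.0764 to 0.52). In Plcg2HET it was 0.382, 0.495, 0.556 and 0.279 in M1, M2, F1 and F3, against -0.451 in M3 and -0.371 in F2. Fold changes also correlated with summed exon length across genes, with Spearman values of 0.268, 0.118 and 0.15 for Plcg2KO, Plcg2HET and Trem2KO against WT. On the first principal component Plcg2HET had an SD of 33.1, against 17.3 in WT, 12.1 in Trem2KO and 3.25 in Plcg2KO. Sequencing dates or batches are not given in the sources used here, so a batch effect and a genotype effect cannot be told apart where they coincide.

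**Figure D1:**
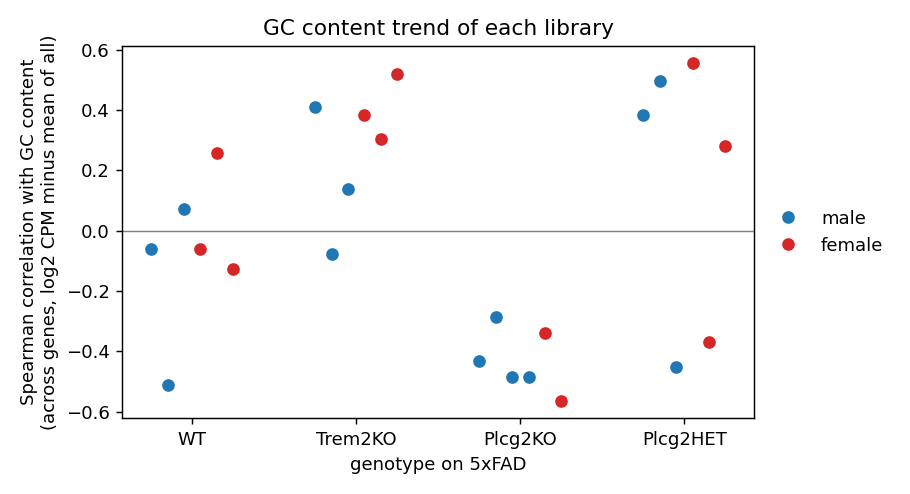
Spearman correlation across genes between GC content and each library's log2 CPM minus the mean of all libraries, by genotype, with 1 point per mouse colored by sex. All 6 Plcg2KO libraries lie below 0, and Plcg2HET M3 (-0.451) and F2 (-0.371) lie apart from the other Plcg2HET libraries.

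The targeted genes were examined first. Plcg2 (chromosome 8, 117498291 to 117635142, plus strand, mm10, 4298 bases of exons) stood at 11.8 ± 3.14 CPM in WT and 0.984 ± 0.159 CPM in Plcg2KO (mean ± SD, n = 6, exact permutation p = 0.00216). The Plcg2KO level was 8.32% of WT, with a log2 fold change of -3.48 (SE 0.20, adjusted p = 3.73e-12). In Plcg2HET, Plcg2 stood at 12.0 ± 4.98 CPM, with a range of 5.89 to 19.8 (SD, n = 6, exact permutation p = 0.922). The log2 fold change of 0.02 had a 95% interval of -0.31 to 0.36 (edgeR, adjusted p = 0.951), which leaves out the change of -0.89 that loss of 1 copy would give at the Plcg2KO residual level. In Trem2KO, Plcg2 stood at 11.4 CPM, with a range of 9.32 to 14.7 (n = 6, exact permutation p = 0.894). The labels do not say which exons were targeted, and counts cover all exons of a gene together.

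Trem2 (chromosome 17, 48346401 to 48352276, plus strand, mm10, 1146 bases of exons) stood at 82.5 ± 34.9 CPM in WT and 6.01 ± 1.21 CPM in Trem2KO, 7.29% of WT (SD, n = 6, exact permutation p = 0.00216). Trem2 was also lower in Plcg2KO, at 19.1 ± 5.39 CPM or 23.1% of WT (log2 fold change -1.89, SE 0.17, adjusted p = 1.39e-08). Plcg2HET held 92.7 ± 34.3 CPM of Trem2 (log2 fold change 0.20, SE 0.16, adjusted p = 0.404). Relative to the mean of 31 microglial markers, Trem2 was lower in Plcg2KO than in WT by a log2 difference of -1.16 (n = 6, exact permutation p = 0.00216).

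**Figure D2:**
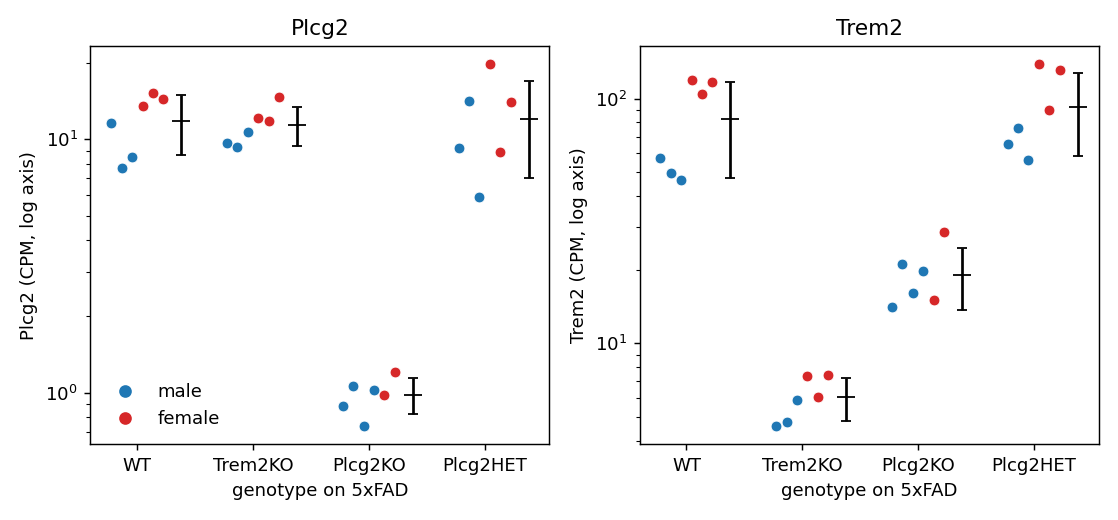
CPM of Plcg2 and Trem2 in each mouse on log axes, by genotype, with 1 point per mouse colored by sex and the mean ± SD beside each group. Plcg2KO libraries hold 0.984 CPM of Plcg2 on average against 11.8 in WT and 12.0 in Plcg2HET, and Trem2 is lower in Plcg2KO (19.1 CPM) than in WT (82.5 CPM).

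All 15 pan-microglial genes, and 17 of 18 genes of the amyloid-responsive state known as disease-associated microglia (DAM) stage 2, were lower in Plcg2KO cortex than in WT cortex. Itgax, the integrin subunit CD11c, fell by 4.49 on the log2 scale (SE 0.22, adjusted p = 1.65e-13), from 23.2 ± 8.55 to 0.902 ± 0.534 CPM (SD, n = 6). Cst7, a cysteine protease inhibitor, fell by 4.01 (SE 0.26, adjusted p = 6.57e-11). Clec7a, the receptor dectin-1, fell by 3.21 and the chemokine gene Ccl3 by 3.22. In all, 2133 of 16316 genes were called, 888 higher and 1245 lower, and 326 were lower by over 2-fold against 40 higher. The largest increases were in Fmo2 (1.70), Plin4 (1.53), which coats lipid droplets, Etnppl (1.46) and Ogn (1.38). In females alone Plin4 stood at 0.42 and was not called (adjusted p = 0.493).

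Of 18 genes of DAM stage 2, the TREM2-dependent state described around plaques, 17 fell and 1 rose in Plcg2KO (the same counts adjusted over the list alone). The gene that rose was Timp2 (0.28), chosen here after its value was seen. Of 7 DAM stage 1 genes 5 fell, 5 adjusted over the list alone, among them Tyrobp (-1.49), the adaptor of TREM2, and Ctsd (-1.22), a lysosomal protease. All 15 pan-microglial genes fell, 15 adjusted over the list alone, including C1qb (-1.25) and Irf8 (-1.29). Of 17 homeostatic microglial genes 11 fell and 1 rose, 12 and 1 adjusted over the list alone. Cx3cr1 (-0.87), the fractalkine receptor, and Olfml3 (-1.16) fell. Of 29 genes of TREM2 and ITAM signalling 20 fell, 24 adjusted over the list alone, including the phosphatase Ptpn6 (-1.69) and the Fc receptor Fcgr2b (-1.07).

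Immune and lysosomal lists were lower as well. Complement genes fell in 8 of 14 and rose in 1, 9 and 1 adjusted over the list alone, with C3ar1 at -1.17. MHC class I genes fell in 10 of 11, 11 adjusted over the list alone, and MHC class II genes in 7 of 8, 7 adjusted over the list alone. B2m stood at -0.70 and Cd74, the class II invariant chain, at -2.24. Lysosomal and phagosomal genes fell in 19 of 28, 21 adjusted over the list alone, with Cd68 at -1.50 and Ctsz at -1.29. Genes of Toll-like receptor and NF-kB inflammation fell in 10 of 28 and rose in 1, 14 and 1 adjusted over the list alone, with Tlr2 at -2.03 and Cd14 at -1.92. Interferon-response genes fell in 16 of 25, 20 adjusted over the list alone, with Bst2 at -1.21 (list adjusted p = 0.0887 with an estimated correlation). In males alone Bst2 stood at -0.87 (adjusted p = 0.192).

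Lists of other cell types were called as well. Reactive astrocyte genes fell in 12 of 26 and rose in 1, 14 and 2 adjusted over the list alone (adjusted p = 0.162 with an estimated correlation). Psmb8, an immunoproteasome subunit that is not specific to astrocytes, stood at -1.17 and Cd44 at -0.71. Disease-associated oligodendrocyte genes fell in 5 of 10 and rose in 1, 6 and 1 adjusted over the list alone (adjusted p = 0.0843 with an estimated correlation). B2m, H2-D1 (-0.79) and H2-K1 (-0.90) in that list are MHC class I genes, which many cell types express. Endothelial genes fell in 7 of 14, 7 adjusted over the list alone, with Tek at -0.82 (list adjusted p = 0.415 with an estimated correlation). In females alone Tek stood at -0.46 (adjusted p = 0.264). Lipid-handling genes fell in 4 of 22, 6 lower and 1 higher adjusted over the list alone, with Gpnmb at -1.82 (list adjusted p = 0.27 with an estimated correlation).

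Meningeal fibroblast genes rose in 8 of 12 and genes of border-associated macrophages in 4 of 11, 8 and 6 adjusted over the list alone, with Dcn at 0.51 and Mrc1 at 0.91. Dcn was not called with GC and length offsets (0.38, adjusted p = 0.0606) or in males alone (0.44, adjusted p = 0.224), and Mrc1 was not called in males alone (0.73, adjusted p = 0.172). Immediate early genes, which neurons induce with activity, rose in 4 of 14, 5 adjusted over the list alone, with Egr1 at 0.73 (list adjusted p = 0.273 with an estimated correlation). Inhibitory neuron genes rose in 3 of 15, 5 adjusted over the list alone, with Gad2 at 0.74 (list adjusted p = 0.0887 with an estimated correlation). Among excitatory neuron genes 1 of 15 rose, 3 adjusted over the list alone, and the list's adjusted p was 0.421 with an estimated correlation. That gene, Slc17a6, stood at 0.42 (adjusted p = 0.0357). Its call was lost without WT F1, F2 or F3 (adjusted p = 0.0832, 0.0815 and 0.0913) or Plcg2KO M3, F1 or F2 (0.0638, 0.117 and 0.0874). In males alone Slc17a6 (0.084), Gad2 (0.38) and Egr1 (0.54) were not called (adjusted p = 0.914, 0.53 and 0.226).

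Of the 36 lists 20 were called, 15 lower and 5 higher, and 12 of these calls held with an estimated correlation. Fold changes correlated with GC content (Spearman -0.316 across genes). The count was 369 in males alone (60 higher, 309 lower), 1011 in females alone (520 and 491) and 3557 with only the 2 groups fitted (1789 and 1768), so the excess of lower genes depended on the fit.

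**Figure D3:**
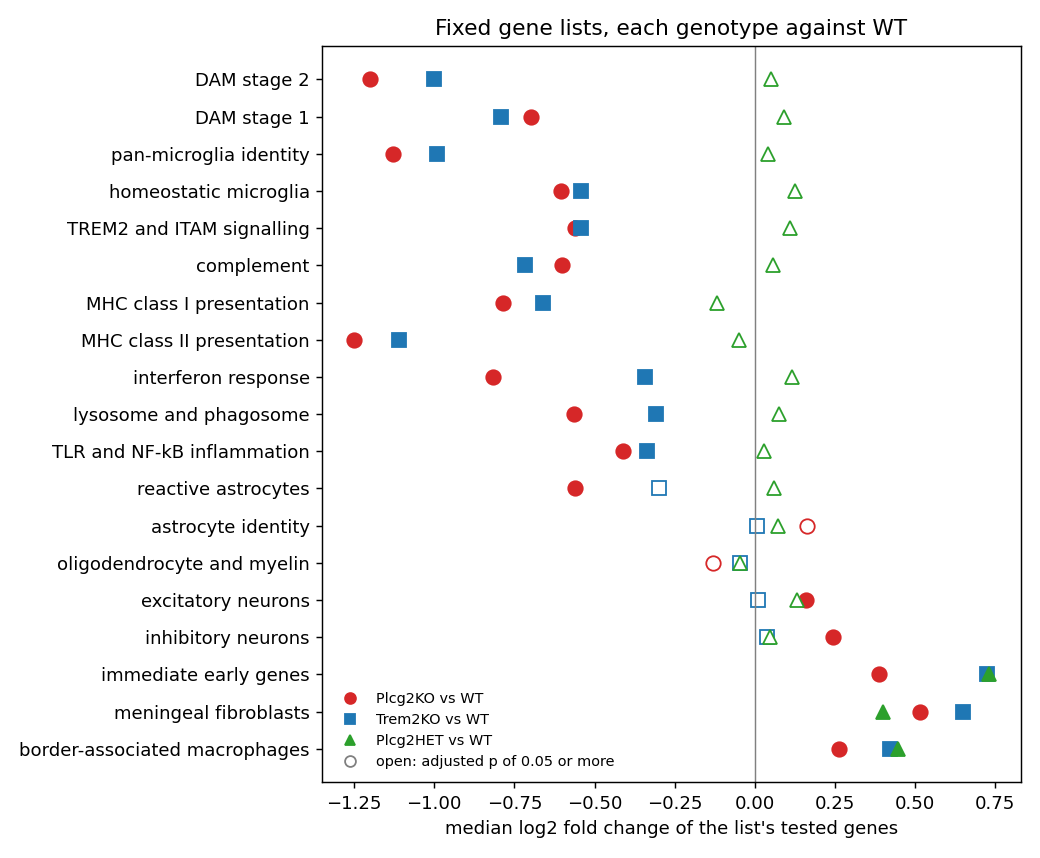
Median log2 fold change of the tested genes in 19 lists, for Plcg2KO, Trem2KO and Plcg2HET each against WT. Filled symbols mark lists called with the preset correlation. DAM stage 2 has medians of -1.20, -1.0 and 0.05 in Plcg2KO, Trem2KO and Plcg2HET.

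All 15 pan-microglial genes and 15 of 18 DAM stage 2 genes were lower in Trem2KO cortex than in WT cortex. Itgax fell by 3.09 on the log2 scale (SE 0.20, adjusted p = 5.97e-11) to 2.73 ± 1.08 CPM and Cst7 fell by 3.02 (SE 0.25, adjusted p = 7.4e-09). Ccl3 stood at -2.62, Clec7a at -2.59 and Ccl6 at -2.34. In all, 2565 genes were called, 1234 higher and 1331 lower, with 208 lower and 30 higher by over 2-fold. The largest increases were in Prg4 (1.26), Eya2 (1.22) and Pcdh1 (1.15).

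DAM stage 2 genes fell in 15 of 18 and rose in 1, 16 and 1 adjusted over the list alone, and DAM stage 1 genes fell in 4 of 7, 4 adjusted over the list alone. Tyrobp stood at -1.36. All 15 pan-microglial genes fell, 15 adjusted over the list alone, with Ptprc, the leukocyte antigen CD45, at -1.48. Homeostatic genes fell in 10 of 17, 10 adjusted over the list alone, with Gpr34 at -1.04. TREM2 and ITAM signalling genes fell in 17 of 29 and rose in 1, 19 and 1 adjusted over the list alone, with Fcgr2b at -1.23. Complement genes fell in 7 of 14 and rose in 1, 8 and 1 adjusted over the list alone. MHC class II genes fell in 7 of 8, 7 adjusted over the list alone, with Cd74 at -2.16. Lysosomal genes fell in 14 of 28 and rose in 1, 15 and 1 adjusted over the list alone, with Ctsz at -0.98. Toll-like receptor and NF-kB genes fell in 12 of 28, 15 lower and 1 higher adjusted over the list alone, with Tlr2 at -1.52.

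MHC class I genes fell in 8 of 11, 8 adjusted over the list alone (list adjusted p = 0.0796 with an estimated correlation). Interferon-response genes fell in 7 of 25, 10 adjusted over the list alone (list adjusted p = 0.297 with an estimated correlation). The lists that were higher numbered 3. Immediate early genes rose in 11 of 14, 13 higher and 1 lower adjusted over the list alone, with Fos at 0.99 (list adjusted p = 0.0613 with an estimated correlation). Meningeal fibroblast genes rose in 9 of 12, 11 adjusted over the list alone, with Col1a2 at 0.94, and border-associated macrophage genes in 5 of 11, 6 adjusted over the list alone, with Stab1 at 0.81. Of 36 lists 14 were called, and 11 calls held with an estimated correlation. Fold changes correlated with GC content (Spearman 0.353 across genes). The count of genes was 72 in males alone (14 higher, 58 lower), 963 in females alone (507 and 456), 4780 with only the 2 groups fitted (2525 and 2255) and 1662 without WT F1.

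In Plcg2HET cortex 4 of 36 lists were called against WT, all higher and none of them microglial. With an estimated correlation 0 of these calls held, and the lowest adjusted p among the 4 was 0.374. Plin4 rose by 3.00 on the log2 scale (SE 0.35, adjusted p = 2.2e-05), from 2.77 ± 0.972 to 22.0 ± 9.66 CPM (SD, n = 6). Hspb1, a small heat shock protein, stood at 1.62, Hif3a at 1.58 and Klf2 at 1.37. In all, 2936 genes were called, 1772 higher and 1164 lower, of which 58 and 59 by over 2-fold. The largest decreases with a protein-coding symbol included Gbp4 (-1.22), an interferon-induced GTPase, and Rnf207 (-0.97).

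DAM stage 2 genes fell in 2 of 18, 1 adjusted over the list alone, with Lpl at -0.77, and DAM stage 1 genes passed in 0 of 7 by edgeR (median 0.09). Homeostatic genes rose in 3 and fell in 3 of 17, 4 and 3 adjusted over the list alone, and pan-microglial genes rose in 1 of 15, 1 adjusted over the list alone. TREM2 and ITAM signalling genes rose in 7 of 29, 7 higher and 1 lower adjusted over the list alone, with Dock2 at 0.64 and Inpp5d at 0.69, whose adjusted p was 0.0505 without the 3 libraries rich in Rn45s. None of these 5 lists was called.

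Immediate early genes rose in 9 of 14, 11 adjusted over the list alone, with Fosb at 1.19 and Arc at 1.13 (list adjusted p = 0.374 with an estimated correlation). Heat shock and unfolded protein genes rose in 8 of 19, 10 adjusted over the list alone, with Pdia4 at 0.56 (list adjusted p = 0.478 with an estimated correlation). Meningeal fibroblast genes rose in 6 of 12, 6 adjusted over the list alone, with Slc13a3 at 0.93 (list adjusted p = 0.478 with an estimated correlation). Border-associated macrophage genes rose in 6 of 11, 7 adjusted over the list alone, with Dab2 at 0.52 (list adjusted p = 0.419 with an estimated correlation). Fold changes correlated with GC content (Spearman 0.348 across genes), and with GC and length offsets 1824 genes were higher and 1780 lower. The count of genes was 5 in males alone, 419 in females alone, 736 with only the 2 groups fitted, 807 without the 3 libraries rich in Rn45s and 1957 without Plcg2HET F1.

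Plcg2KO was compared directly with Trem2KO to ask where the 2 knockouts differ. Trem2 was 1.80 higher and Plcg2 3.44 lower in Plcg2KO on the log2 scale. Itgax was lower in Plcg2KO than in Trem2KO (-1.40, SE 0.22, adjusted p = 0.000765), as were Klk6 (-1.14), a protease of oligodendrocytes, and Heyl (-1.02), a Notch target. Etnppl (1.48), Fmo2 (1.19) and Cd38 (0.90) were higher. Among homeostatic genes, P2ry12, a purinergic receptor, was higher in Plcg2KO (0.64, SE 0.12, adjusted p = 0.00283), at 44.2 ± 7.76 against 28.6 ± 3.34 CPM (SD, n = 6). Mertk, a phagocytic receptor, was also higher (0.47), and Fcrls was lower (-0.61).

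DAM stage 2 genes were lower in Plcg2KO in 6 of 18, 7 lower and 1 higher adjusted over the list alone, with Cd9 at -0.56. Lysosomal genes were lower in 9 of 28, 16 lower and 1 higher adjusted over the list alone, with Man2b1 at -0.44. Endothelial genes were lower in 6 of 14, 8 adjusted over the list alone, with Tek at -0.74. Pericyte and smooth muscle genes were lower in 2 of 11, 2 adjusted over the list alone, with Notch3 at -0.81. Reactive astrocyte genes were lower in 7 of 26 and higher in 1, 8 and 1 adjusted over the list alone. The 1 that was higher was Lcn2. It stood at 4.07 in males alone and 2.9 in females alone and was called in neither (adjusted p = 0.0551 and 0.121). For each of these 5 called lists the adjusted p was 0.752 with an estimated correlation. The number of lists called was 10 with the replicate code as a block, 10 without the sex term and 8 with GC and length offsets.

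In all, 2684 genes were called between the knockouts, 1245 higher and 1439 lower in Plcg2KO. Fold changes correlated with GC content more than in any other comparison (Spearman -0.644 across genes), and with GC and length offsets 1040 genes were called, of which 695 were among those called without the offsets. The count was 1073 with the replicate code as a block, 11 in males alone, 6 in females alone, 6712 with only the 2 groups fitted, and 769, 1563, 1060, 1142 and 1319 without Trem2KO M1, F1, F3, Plcg2KO F1 and F2, respectively.

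The effects of both knockouts were then set against each other. Of the genes lower in Plcg2KO (1245) and in Trem2KO (1331), 580 were lower in both, where independent lists would share 101.6. Of those higher, 333 were higher in both, where independent lists would share 67.2, and 1 gene went opposite ways. Plcg2HET and Trem2KO, each against WT, also shared more genes than independent lists would. They shared 596 higher (134 expected) and 249 lower (94.9 expected), with 55 opposite and a correlation of 0.432. Fold changes of both rose with GC content (Spearman 0.348 and 0.353), while those of Plcg2KO fell with it (-0.316). The simulations and separate WT libraries described below were run only for the 2 knockouts. Chance could not be excluded for the number of genes called in Plcg2HET, as described further below. Plcg2HET and Plcg2KO shared 209 higher (96.4 expected) and 166 lower (88.8 expected), with 85 opposite and a correlation of 0.207. Of the 580 genes lower in both knockouts, 53 were lower and 7 higher in Plcg2KO than in Trem2KO, and their median log2 fold changes were -0.85 and -0.74. For the knockouts the correlation of fold changes across genes was 0.64 and their covariance 0.096, but all these comparisons use the same WT libraries. Simulations of unchanged groups and WT alike, with genes drawn independently, gave a correlation of 0.502, a covariance of 0.0205 and 0 shared calls (medians of 20). Trends across genes in the real WT libraries, such as that with GC content, were absent there. These values may therefore understate what shared WT libraries give. With separate WT libraries for each knockout (3 each), medians were 297 genes lower in both, 74 higher in both, a correlation of 0.472 and a covariance of 0.0791. Genes are not independent replicates in these correlations.

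**Figure D4:**
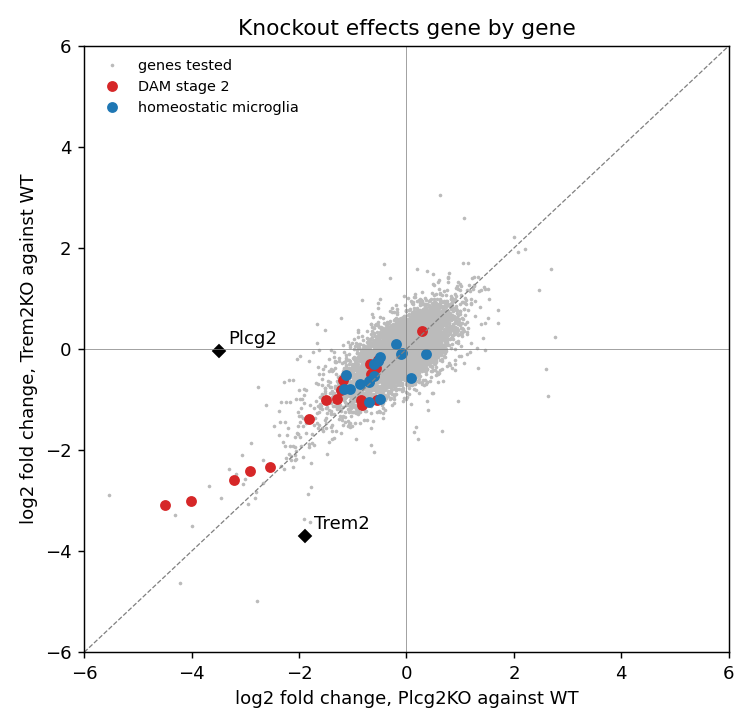
Log2 fold change of each tested gene in Plcg2KO (horizontal) and in Trem2KO (vertical), both against WT, with DAM stage 2 genes in red, homeostatic microglial genes in blue and the targeted genes as diamonds. The dashed line marks equal change. Itgax (-4.49 and -3.09) and Cst7 (-4.01 and -3.02) lie lowest among DAM stage 2 genes.

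Plcg2KO was compared with the mice labelled heterozygous, in which Plcg2 stood at 101% of WT. Itgax was lower in Plcg2KO than in Plcg2HET (log2 fold change -4.85, SE 0.22, adjusted p = 3.03e-14), and Cst7 (-4.25), Plcg2 (-3.50), Cd68 (-1.84) and the integrin subunit Itgb2 (-1.27) were lower too. DAM stage 2 genes fell in 15 of 18 and rose in 1, and all 15 pan-microglial genes fell, with the same counts adjusted over the list alone. TREM2 and ITAM signalling genes fell in 23 of 29 and lysosomal genes in 21 of 28, 25 and 21 adjusted over the list alone. Interferon-response genes fell in 22 of 25, 22 adjusted over the list alone (list adjusted p = 0.11 with an estimated correlation). In all, 5746 genes were called, 2445 higher and 3301 lower, and 18 of 36 lists were called, of which 9 held with an estimated correlation. The Spearman correlation of fold changes with GC content was -0.501 across genes. The count of genes was 1581 in males alone, 1664 in females alone, 3512 with only the 2 groups fitted and 3113 without the libraries rich in Rn45s.

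Sex was a term of the model shared by the 4 genotypes. Of 387 genes called between the sexes, 371 were higher and 16 lower in females, and those with the smallest p were Kdm5d, Xist, Eif2s3y, Ddx3y and Uty, all on the sex chromosomes. All 15 pan-microglial genes were higher in females (median 0.57), as were 13 of 18 DAM stage 2 genes (median 0.57) and 20 of 25 interferon-response genes (median 0.68), with 15, 16 and 22 adjusted over the list alone. Of 36 lists 17 were called, 16 higher and 1 lower in females, and 13 held with an estimated correlation. Fold changes between the sexes correlated with summed exon length (Spearman -0.353 across genes) and with GC content (0.171), and the length trend was -0.419, -0.232 and -0.449 in WT F1, F2 and F3. Without the libraries rich in Rn45s 146 genes were called.

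No gene's genotype effect was called different between the sexes by edgeR. For Plcg2KO, Plcg2HET and Trem2KO against WT 0 genes were called, with 1271, 887 and 474 genes at an unadjusted p under 0.05. Chance alone would give about 5% of the 16316 genes tested. The count for Plcg2HET lay close to that share and the count for Trem2KO below it. DESeq2 called 5, 1 and 0 genes. For Plcg2KO these were Dlk1, Plau, Dcstamp, Epas1 and Hpse and for Plcg2HET Ggnbp2os, named here after their values were seen.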

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

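Of the tests weighed below, those for GC content, for reads of the targeted allele, for microglial number in Plcg2HET, for genotype labels, and the permutation tests of list means were chosen only after the results were seen.

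Lower DAM stage 2 genes in Plcg2KO and Trem2KO were weighed against fewer microglia as the whole cause. Homeostatic microglial genes fell less than DAM stage 2 genes. The difference in list medians was 0.597 in Plcg2KO (SD 0.171 over libraries) and 0.462 in Trem2KO (SD 0.141). This does not exclude a uniform loss of microglial RNA as the whole cause. In bulk cortex, RNA of homeostatic genes from other cell types would lessen their fall, which was not tested. Pan-microglial genes fell nearly as far as DAM stage 2 genes, with medians of -1.13 and -1.20 in Plcg2KO and -0.99 and -1.0 in Trem2KO. The answer thus depended on the list chosen, and fewer microglia may be part of the change. Bulk RNA cannot separate that part from lower expression per cell. After GC and length offsets the DAM stage 2 medians were -1.14 (SD 0.259 over libraries, -1.20 before) and -0.938 (SD 0.253, -1.0 before), which excludes a bias by GC content or gene length as the cause.

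Plcg2 was not lower in Plcg2HET than in WT. Reads from the targeted allele could not fill the gap, since Plcg2KO held 8.32% of the WT level and no Plcg2KO library more than 10.2%. More microglia did not hide a fall of -0.89 in the group as a whole. The difference relative to microglial markers was -0.09 (exact permutation p = 0.00216 against -0.89, n = 6). The value of -0.89 for 1 targeted copy came from the CPM of Plcg2KO. Relative to markers Plcg2KO stood at -2.17, so 1 copy would give a smaller change there, which was not tested. The test used the group mean and does not speak for single libraries. Wrong genotype labels were left open by the test: 2 of 6 Plcg2HET libraries, M3 (-0.60) and F2 (-0.47), lay below the lowest WT library (-0.25), and the other 4 lay between -0.15 and 0.39. A mix of carriers and non-carriers and higher expression from the remaining copy cannot be told apart with these data, and M3 and F2 also differed from the other Plcg2HET libraries in GC trend.

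Whether chance could be excluded was asked by splitting the same libraries into other groups of the same sizes, 60 splits per comparison with the real one included. Chance could be excluded for the genes called in Plcg2KO against WT (1 of 60 splits as large, real value 2133 and the highest of the other splits 437). The same holds for Trem2KO against WT (1 of 60, real value 2565 and the highest of the other splits 1029). It also holds for Plcg2KO against Trem2KO (1 of 60, real value 2684 and the highest of the other splits 1). These splits cannot tell a genotype effect from a technical shift that follows genotype, such as the GC trend. With GC and length offsets 1040 genes were called between the knockouts, of which 695 were among those called without the offsets. For the sexes another split gave more genes than the real one (2 of 60, real value 387 and the highest of the other splits 753). That share lies under the limit of 0.05 of splits fixed beforehand for excluding chance. With another split larger, chance was still not clearly excluded for the number of genes called between the sexes. Chance could not be excluded for Plcg2HET against WT (4 of 60, real value 2936 and the highest of the other splits 5971) or for Plcg2KO against Plcg2HET (3 of 60, real value 5746 and the highest of the other splits 6550).

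Chance could not be excluded for the number of lists called in any of the 5 comparisons of genotypes, and no splits were run for the lists called between the sexes. As many lists were called in 10 of 60 splits for Plcg2KO against WT (real value 20 and the highest of the other splits 23) and in 42 for Plcg2HET (4 and 19). The splits with as many were 20 for Trem2KO (14 and 23), 34 for Plcg2KO against Trem2KO (5 and 19) and 9 for Plcg2KO against Plcg2HET (18 and 21). Medians of the other splits were 14, 6 and 11 lists for Plcg2KO, Plcg2HET and Trem2KO against WT. They were 5 for Plcg2KO against Trem2KO and 11 for Plcg2KO against Plcg2HET. Splits were run for the interactions of sex with Plcg2HET and Trem2KO, not with Plcg2KO. The real value was 0 for both, so 40 of 40 splits had as many genes by construction and say nothing about chance (the highest of the other splits was 5423 for Plcg2HET and 132 for Trem2KO).

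Because of these splits, the mean log2 CPM of each list was tested by exact permutation of genotype. A version that ignored sex was run first. A version within sex followed because Plcg2KO has 4 males and 2 females. Within sex, and after adjustment over 36 lists, 18 of the 20 called lists passed for Plcg2KO against WT, 0 of 4 for Plcg2HET, 14 of 14 for Trem2KO, 4 of 5 for Plcg2KO against Trem2KO and 18 of 18 for Plcg2KO against Plcg2HET. In the first version these were 17, 0, 13, 2 and 18. Over all 36 lists, called by camera or not, 22, 0, 22, 12 and 19 passed within sex, in the same order. Passing was thus not limited to lists called by camera. Genes next to the Plcg2 locus passed in Trem2KO against WT (0.213, adjusted p = 0.0112 by exact permutation within sex). Genes next to the Trem2 locus passed in Plcg2KO against WT (-0.293, adjusted p = 0.00735 by the same test). Within sex, the smallest p possible for Plcg2HET was 0.005, from 400 arrangements. The immediate early, heat shock and border-associated macrophage lists had that p, with an adjusted p of 0.06. The count of 0 of 4 thus does not show that these lists were unchanged.

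Values far from the other libraries of their group were found in 8 of 180 tests, where chance alone would give about 5%. The Rn45s share was high in WT F1 (9.59%) and Plcg2HET F3 (29%) and low in Trem2KO F1 (0.334%), and the TMM factor was low in Plcg2HET F3 (0.716). Of list means relative to WT, Plcg2KO F2 lay above the rest of its group for homeostatic microglia (-0.30) and Plcg2KO M2 below it for choroid plexus and ependyma (-0.41). Plcg2HET F1 lay above its group for T and NK cells (0.43) and Plcg2HET F3 for border-associated macrophages (0.84).

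With the preset correlation, the genotype effect was called different between the sexes for 18 of 36 lists in Plcg2KO against WT. The same was called for 5 of 36 lists in Plcg2HET and 13 of 36 in Trem2KO. With an estimated correlation 0 were called. No splits were run for these list tests, and the preset test also called lists in other splits of the genotypes, as given above. Chance was therefore not excluded for the differences below. These tests were first reported only where both correlations passed. The preset test alone was taken after that had given 0. For Plcg2KO (lowest adjusted p = 0.214 with an estimated correlation), the female minus male difference in medians was -0.54 for DAM stage 2, -0.064 for DAM stage 1, -0.24 for homeostatic microglia, -0.39 for pan-microglia identity and -0.17 for TREM2 and ITAM signalling. It was -0.44 for interferon response, -0.42 for lysosome and phagosome, -0.29 for lipid handling, -0.47 for TLR and NF-kB inflammation, -0.33 for disease-associated oligodendrocytes and -0.33 for oxidative phosphorylation. It was 0.23 for excitatory neurons, 0.21 for inhibitory neurons, 0.27 for pan-neuronal genes, 0.51 for endothelial cells, 0.30 for striatal, 0.52 for hippocampal and 0.45 for thalamic tissue.

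For Trem2KO (lowest adjusted p = 0.139 with an estimated correlation) the difference was -0.52 for DAM stage 2, -0.28 for DAM stage 1, -0.34 for homeostatic microglia, -0.31 for pan-microglia identity and -0.23 for TREM2 and ITAM signalling. It was -0.19 for interferon response, -0.19 for lysosome and phagosome, -0.26 for TLR and NF-kB inflammation, 0.18 for excitatory neurons, 0.099 for inhibitory neurons, 0.11 for pan-neuronal genes, 0.51 for endothelial cells and 0.27 for striatal tissue. For Plcg2HET (lowest adjusted p = 0.181 with an estimated correlation) it was -0.25 for DAM stage 2, -0.12 for interferon response, 0.30 for endothelial cells, 0.31 for striatal tissue and -0.49 for oxidative phosphorylation.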

How the results depend on the processing

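The expected counts, the GC and length offsets and the fit without libraries rich in Rn45s were chosen only after the data were seen. Of 2440 values of named genes under the alternatives, 2217 stayed on their side of the threshold, 209 lost the call, 14 gained one and 0 reversed. A reversal was counted only where the main or the alternative fit made a call. Changes of direction without a call were counted as unchanged. Of 2412 values with 1 library left out, 2349 stayed on their side by the same count, as did 1000 of 1080 list values. RLE size factors, the count filters, the sex term and the expected counts moved no count of genes by over 1.5-fold. The cause of the changes below was not tested.

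In males only, the genes called were 369 for Plcg2KO against WT, 5 for Plcg2HET, 72 for Trem2KO, 11 for Plcg2KO against Trem2KO and 1581 for Plcg2KO against Plcg2HET. The 5 genes in Plcg2HET males, named after their values were seen, were Ptpn7 (-1.72), Plin4 (3.24), Fjx1 (-0.78), Hif3a (1.59) and Mex3b (-0.92). In females only, the counts were 1011, 419, 963, 6 and 1664 in the same order. These fits hold fewer libraries, and of 201 values of named genes 108 lost the call in males only and 56 in females only. With only the 2 groups compared, the counts were 3557, 736, 4780, 6712 and 3512.

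Without the libraries rich in Rn45s, 807 genes were called for Plcg2HET against WT, 3113 for Plcg2KO against Plcg2HET and 146 between the sexes. With GC and length offsets, 1040 genes and 8 lists were called for Plcg2KO against Trem2KO, and the knockouts shared 990 lower and 599 higher genes. With the replicate code as a block, the same comparison gave 1073 genes and 10 lists, and without the sex term 10 lists. Replicate codes did not pair the libraries: 6 of 23 correlated best with a library of their own code. With separate WT libraries for each knockout, 297 lower and 74 higher genes were shared and the correlation was 0.472.

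With an estimated correlation, the lists called were 12 for Plcg2KO against WT, 0 for Plcg2HET, 0 for Plcg2KO against Trem2KO and 9 for Plcg2KO against Plcg2HET. DESeq2 called 5 genes for the interaction of sex with Plcg2KO, Dlk1 (1.56), Plau (-1.25), Dcstamp (-7.31), Epas1 (0.86) and Hpse (-1.53), and 1 for Plcg2HET, Ggnbp2os (-1.84).

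With 1 library left out, the genes called ranged from 1441 to 2267 for Plcg2KO against WT, from 1957 (without Plcg2HET F1) to 4369 for Plcg2HET, from 1662 (without WT F1) to 2597 for Trem2KO and from 4475 to 7509 for Plcg2KO against Plcg2HET. For Plcg2KO against Trem2KO they ranged from 769 (without Trem2KO M1) to 2796, with 1563 without Trem2KO F1, 1060 without Trem2KO F3, 1142 without Plcg2KO F1 and 1319 without Plcg2KO F2.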

Other observations

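The gene lists and all tests in this part were chosen only after the results were seen.

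Glucocorticoid-responsive genes were higher in Plcg2HET and Plcg2KO than in WT. Of 16 such genes 12 were higher in Plcg2HET (median 0.66, p = 0.000488 with an estimated correlation by camera), 12 in Plcg2KO (0.52, p = 0.00253) and 2 in Trem2KO (0.10, p = 0.38). Sgk1 stood at 1.10 in Plcg2HET and 0.95 in Plcg2KO, and Tsc22d3 at 0.60 and 0.70. Medians per library were taken relative to the mean of the WT libraries of the same sex. They were 0.36 to 0.947 in Plcg2HET, 0.247 to 0.848 in Plcg2KO and -0.051 to 0.261 in Trem2KO. The WT range of -0.052 to 0.073 is centred and narrowed by construction, since each WT library is part of its own reference.

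Technical causes of the glucocorticoid-responsive pattern in Plcg2HET were tested. The median of 0.659 was 0.575 after GC and length offsets (SD 0.151 over libraries) and 0.507 without the libraries rich in Rn45s (SD 0.124), so neither was the cause. Another time of day at collection was left open, since Arntl, Npas2 and Clock had a median of 0.042. Of 14 circadian clock genes 5 were higher in Plcg2HET and 3 in Plcg2KO, but also 6 in Trem2KO. In Trem2KO glucocorticoid-responsive genes were not called as a set. The medians of the clock genes were 0.253 in Plcg2HET, 0.208 in Plcg2KO and 0.0619 in Trem2KO. Without adjustment over lists, the clock set passed camera in each of these genotypes with the preset correlation. With an estimated correlation the clock set passed only in Plcg2HET. Handling or collection cohort and genotype cannot be told apart, because the animal numbers of the genotypes lie in separate ranges and dates are not given in the sources used here. The pattern could therefore be one of stress at collection as well as of Plcg2.

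The mouse gene for the amyloid precursor protein, App, was examined, since reads of the human transgene may be counted there in part. App was higher in Trem2KO (0.30, adjusted p = 0.0368) and did not pass in Plcg2KO (0.29, adjusted p = 0.0521).

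Plcg2 relative to 31 microglial markers was higher in Trem2KO than in WT by a log2 difference of 0.63 (n = 6, exact permutation p = 0.00216), while its CPM was 96.2% of WT. Homeostatic P2ry12 did not pass in Plcg2KO against WT (0.08, adjusted p = 0.723) and was lower in Trem2KO (-0.57).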
